A study of Homo sapiens with 24 samples.

How the data were processed

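The data are gene-level RNA-seq values of 24 libraries of the human induced pluripotent stem cell line WTC, in 8 groups of 3 biological replicates per the labels. The groups combine genotype (wild type or ZO1 knockdown), culture (standard plate or transwell) and treatment (untreated or BMP4). Doxycycline was given only to knockdown cells per the labels, and the file headers of the 6 standard knockdown libraries name 14 days of it, so genotype and doxycycline are one factor here. The treatment label of the wild-type BMP4 groups gives 48 h, and the duration in the knockdown groups is not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

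The deposited values are estimated counts per gene, one file per library, not normalized between libraries. Per the submitters' processing notes reads were trimmed with Trimmomatic 0.36, checked with FastQC 0.11.9 and MultiQC 1.9, and quantified with Salmon 0.14.2 against GRCh38. The annotation release, the step from transcripts to genes, any filter and any use of strand are not given in the sources used here. Per the labels' protocols RNA was extracted with an RNeasy kit. The standard-plate libraries were made with a stranded mRNA preparation kit and the transwell libraries with poly-T beads, random hexamers and second-strand dUTP. Culture format and library protocol therefore coincide, and depth differs with both, at 74727749 to 97309090 counts per library on standard plates and 16135777 to 24187600 on transwells. A lower depth makes low genes harder to call on transwells, and a protocol can favour some transcripts, so a direct comparison of the formats compares sets of libraries. The files list 34402 genes each, of which 6008 have no symbol in the files, and 34329 IDs were matched to the reference annotation, which was used for symbols and coordinates. The reference is GENCODE's GRCh38 annotation, whose release may differ from the one the authors used.

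The estimated counts were rounded to whole numbers. No pair of replicates held identical values, and the chi-square per degree of freedom between replicates of a group was at least 7.47, so each library counted as a sample of its own. Genes were filtered with edgeR's filterByExpr by group (minimum count 10, minimum total 15). Libraries were scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest; edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 groups of a culture format were fitted together, so that they shared one estimate of the spread, and the formats apart. Interactions with culture and the comparisons of formats used one fit of all 24 libraries. Levels are CPM from the library totals. A gene at 0 in all libraries of a group was given only a bound, taken from a floor of 3 counts per library, and no interaction value. Such floors cover counting error only.

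Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the 26 lists of a comparison. The correlation was also estimated per list, and fry was run, which asks whether a list's genes move on balance one way and compares them with no others. The lists were written from general knowledge before the data were examined and cover junctions, pluripotency, germ cell, germ layer and extraembryonic markers, signalling responses, stress, metabolism and proliferation. They hold 441 entries for 423 genes, so some genes stand in more than 1 list, and 9 genes are not in the files. Members that changed are counted over all genes tested and, in parentheses, adjusted over the list alone. TJP1 was left out of its own list. 1 list is counted but not reported here.

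The design, the lists, the alternatives and the rule for the genes named were set before the data were examined. By that rule each knockdown comparison could name the 6 largest rises and the 6 largest falls among called genes with an average log2 CPM of at least 1 and replicates that do not overlap between groups, and up to 3 members per list by adjusted p. For BMP4 comparisons and interactions the numbers were 4 and 2. Clone, LOC and antisense names were left out. NANOS3, SOX17, PRDM1, TFAP2C, TBXT, CDX2, ISL1, POU5F1, NANOG, SOX2 and ID1 could be named whatever their result. The rule allows a part of these genes to be printed, in its order. In the BMP4 comparisons and interactions list members and the genes always allowed were preferred to the largest changes, many of which involve a group at 0, and that preference was set after the values were seen.

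The alternatives were DESeq2 1.42.0 in place of edgeR, RLE scaling, no low-count filter or one at 5 CPM in 3 libraries, an adjusted p under 0.01, a fold threshold of 2, the replicate number as a block, all 24 libraries or only the 6 compared in the fit, each library left out in turn, and length offsets, which were not run since the files give no lengths. Thinning of the standard libraries to the depth of the transwell library of the same genotype, treatment and number, and of all standard libraries to the depth of the smallest of the 24, were added after the data were seen. For comparisons of 3 against 3 libraries all 10 splits were refitted, and for interactions 24 seeded splits, a number lowered for run time after a first set of draws had been seen. The fits were tested on simulated counts with 200 genes changed. These were drawn only from genes with higher mean counts, 66 or 67 per fold, so the shares recovered do not cover low genes. In the design of the knockdown in untreated standard cells, over 17246 genes, 53.7%, 68.7% and 87.9% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered. On transwells, over 15267 genes, the shares were 29.9%, 82.1% and 100.0%. For the interaction on transwells, over 15274 genes, they were 8.96%, 55.2% and 90.9%. Of the calls in these designs, in the same order, 6.14%, 7.45% and 5.45% fell on unchanged genes.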

Results

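RNA was measured in 24 poly(A)-selected libraries of WTC, an established human induced pluripotent stem cell line. The cells were either wild type or carried a knockdown of ZO1, the scaffold protein of tight junctions, which is encoded by TJP1. Each genotype was grown on standard plates or on transwells, permeable membrane inserts that give access to the basal side of the cells. In each format the cells were left untreated or given BMP4, a morphogen that drives pluripotent cells towards gastrulation-stage fates. The 8 groups held 3 biological replicates each, and the treatment label of the wild-type BMP4 groups gives 48 h. For the knockdown groups the duration is not given in the sources used here, so comparisons of genotypes with BMP4 could include a difference in duration. Per the labels doxycycline was given to knockdown cells and not to wild-type cells, so the 2 cannot be separated in any comparison of genotypes. The estimated counts summed to between 74727749 and 97309090 per library on standard plates and between 16135777 and 24187600 on transwells. Library preparation also differed between standard plates and transwells, so the culture formats were fitted apart wherever the comparison allowed. Levels below are CPM, counts scaled to a common library total, as mean ± SD of 3 libraries. Log2 fold changes from edgeR are given ± an approximate SE. It is the absolute log2 fold change divided by the square root of edgeR's F statistic. The count of list members that changed, over all genes tested, is followed in parentheses by the count adjusted over the list alone. Genes named for the largest change had an average of at least 1 on the log2 CPM scale.

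The target was lower in every library labelled as a knockdown. TJP1 (ENSG00000104067, protein-coding, chromosome 15 from 29699367 to 29968865 on the minus strand of GRCh38) ranged from 77.3 to 172 CPM in the 12 wild-type libraries and from 0.0206 to 3.40 CPM in the 12 knockdown libraries. On standard plates untreated cells had 168 ± 3.55 CPM in wild type and 0.943 ± 0.691 CPM in the knockdown, a log2 fold change of -7.47 ± 0.54. On transwells the untreated values were 107 ± 15 and 2.32 ± 1.40 CPM, a log2 fold change of -5.58 ± 0.40. With BMP4 the log2 fold change was -8.01 ± 0.57 on standard plates and -7.17 ± 0.47 on transwells. Every library matched its genotype label.

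**Figure D1:**
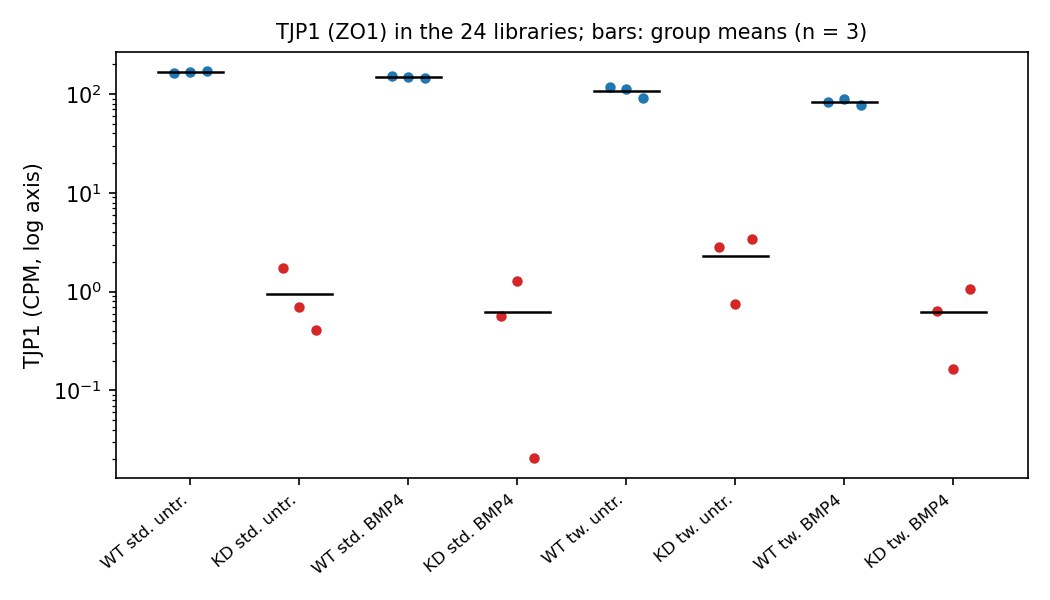
TJP1 in each of the 24 libraries, in CPM on a log axis, by group. Points are libraries and bars are group means; all 12 knockdown libraries lie at or below 3.40 CPM and all 12 wild-type libraries at or above 77.3 CPM.

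The first comparison asked what the knockdown changed in pluripotent cells on standard plates. Genes lower in the knockdown included CDKN1A, the cell cycle inhibitor p21 (-2.15 ± 0.12), ZMAT3 (-1.23 ± 0.10) and PHLDA3 (-1.36 ± 0.14). Targets of the mechanosensitive coactivators YAP and TAZ fell as a list, 10 (12) of 22 members with 1 (1) rising. AMOTL2 changed by -1.86 ± 0.08, CCN2 by -1.76 ± 0.09 and CCN1 by -1.73 ± 0.12. Pluripotency genes shifted slightly upwards: 7 (10) of 19 rose and 2 (3) fell, with DNMT3B, a de novo DNA methyltransferase, at 0.55 ± 0.03, DPPA4 at 0.35 ± 0.03 and TERF1 at 0.36 ± 0.04. These 2 lists were called by camera and kept their calls when the correlation between genes was estimated (adjusted p = 0.0224 and 0.0349).

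Genes of the ATF4 amino acid and stress response rose as a list in the same comparison, 9 (11) of 20 members, although GDF15, a member of this list, fell by 1.87 on the log2 scale. The camera call for this list was lost with an estimated correlation (adjusted p = 0.0616), as was that for the FGF and ERK list (adjusted p = 0.509). In the latter 4 (4) of 14 members fell, including FOSL1 (-2.11 ± 0.18) and EGR1 (-0.81 ± 0.13), both immediate early transcription factors. The largest rises were in ZNF10, a KRAB zinc finger repressor (4.25 ± 0.16, from 3.75 ± 0.614 to 70.4 ± 5.05 CPM), CLIC5 (2.68 ± 0.74) and XKR4 (1.95 ± 0.31). Among the largest falls were ANKRD1 (-3.35 ± 0.49), TNNT2, which encodes cardiac troponin T (-2.88 ± 0.20), and PDGFB (-2.70 ± 0.33). GATA5 was at 0 in all 3 knockdown libraries, which put it at least 1.57-fold lower. ID1, a direct BMP target, rose from 22.6 ± 3.94 to 39.3 ± 1.58 CPM and NANOG from 95.2 ± 11.1 to 127 ± 3.45 CPM, while SOX2 was not called (edgeR adjusted p = 0.596). No member of the primitive streak or definitive endoderm lists was called, and the tight junction and apical polarity list had 2 (3) rising and 1 (3) falling of 27 besides TJP1. Of the naive pluripotency list 2 (2) of 9 rose and 0 (0) fell, without a call for the list (camera adjusted p = 0.611). In all, 1583 of 17512 genes tested changed, 740 higher and 843 lower, 204 of them by at least 2-fold, and 5 of 26 lists were called. The count was 943 without wild-type replicate 2 and 967 without knockdown replicate 1. CLIC5 lost its call without knockdown replicate 3 or any 1 wild-type library (edgeR adjusted p from 0.0653 to 0.175) and without the low-count filter (0.0518). With all standard libraries thinned to one depth CLIC5, ANKRD1 and GATA5 were not called (edgeR adjusted p = 0.3, 0.0724 and 0.324). DESeq2 called 2499 genes and one fit of all 24 libraries 705.

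BMP4 treatment of wild-type cells on standard plates addressed how cells with ZO1 responded to the morphogen. BMP targets rose: 10 (10) of 14 members of the BMP response list, with ID1 going from 22.6 ± 3.94 to 191 ± 7.43 CPM and ID4 changing by 3.94 ± 0.11. The same cells did not lose pluripotency genes as a list, since 10 (10) of 19 members rose and 3 (3) fell. SOX2 went from 242 ± 5.05 to 466 ± 19.1 CPM (0.98 ± 0.09), and PRDM14 (1.14 ± 0.06) and PODXL (0.94 ± 0.04) also rose. Markers of primitive streak rose in 8 (8) of 13 cases, of amnion in 8 (8) of 15 and of lateral and extraembryonic mesoderm in 5 (5) of 13, with 2 (2) falling, but from near 0 to low levels. TBXT (brachyury) reached 2.09 ± 0.22 CPM and TFAP2A 9.56 ± 1.58 CPM. EVX1 and HAND1, at 0 before treatment, reached 0.968 ± 0.184 and 0.913 ± 0.233 CPM, at least 27.0-fold and 25.4-fold higher. CDX2, also at 0 before, was uneven between replicates, at 0.227, 0.423 and 1.86 CPM. FGF and ERK response genes fell, 11 (11) of 14, including the ERK phosphatase DUSP6 (-4.88 ± 0.19) and the feedback inhibitor SPRY4 (-2.32 ± 0.07).

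NODAL pathway genes in the same wild-type cells moved both ways: LEFTY1 (-2.71 ± 0.10) and LEFTY2 (-2.03 ± 0.11), secreted NODAL inhibitors, fell, and the list as a whole was not called (camera adjusted p = 0.865). ATF4 response genes fell in 14 (15) of 20 cases, for example ASNS, the asparagine synthetase (-0.88 ± 0.06). All 13 mitochondrially encoded genes rose, with the share of counts from mitochondrial genes at 4.70 ± 0.416% before and 7.38 ± 0.551% after treatment. That list lost its call with an estimated correlation (adjusted p = 0.203). Of the endothelium and blood list 6 (7) of 12 fell, ERG at -3.67 ± 0.27 (adjusted p = 0.101 with an estimated correlation). Of the actin and SRF list 10 (11) of 15 fell (adjusted p = 0.175 with an estimated correlation). The 9 other called lists held with an estimated correlation, and 5854 genes changed, 2859 higher and 2995 lower, of which 1091 by at least 2-fold.

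Knockdown cells on the same plates responded to BMP4 with gastrulation-stage genes. All 14 (14) of 14 BMP response genes rose, ID1 going from 39.3 ± 1.58 to 541 ± 17.7 CPM and NOG, a secreted BMP antagonist, changing by 10.69 ± 0.18. Primitive streak genes rose in 12 (12) of 13 cases: TBXT reached 209 ± 10.4 CPM from 0.0619 ± 0.0608 CPM, and EVX1, at 0 before treatment, was at least 4117-fold higher. Amnion markers rose in 12 (12) of 15 cases, with TFAP2A at 314 ± 10.5 CPM and ISL1 at 31.9 ± 0.521 CPM, and lateral and extraembryonic mesoderm markers in 10 (10) of 13, with HAND1 at 61.8 ± 1.59 CPM. Pluripotency genes fell, 13 (15) of 19 with 2 (2) rising, and SOX2 dropped from 255 ± 10.7 to 11 ± 2.09 CPM and NANOG from 127 ± 3.45 to 86.4 ± 4.90 CPM. With BMP4 NANOG was thus near its level in wild-type standard cells, 81.6, 85.3 and 84.8 CPM per library. SOX17 and NANOS3, both at 0 in untreated knockdown cells, reached 13.2 ± 1.15 and 5.89 ± 1.33 CPM, at least 346-fold and 154-fold higher.

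WNT response genes also rose in these cells, 14 (14) of 16, with NOTUM, a WNT deacylase, at 8.63 ± 0.25. YAP and TAZ targets rose in 15 (15) of 22 cases (AMOTL2 3.50 ± 0.08). Mesenchyme and EMT genes rose in 11 (11) of 17, led by fibronectin, FN1 (5.66 ± 0.08), a call lost with an estimated correlation (adjusted p = 0.21). The 8 other called lists held. In total 9039 genes changed, 4496 higher and 4543 lower, 3052 of them by at least 2-fold.

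Whether the knockdown altered the BMP4 response on standard plates was tested as an interaction. The response of knockdown cells exceeded that of wild-type cells for 13 (14) of 14 BMP response genes, among them BAMBI (3.56 ± 0.12), SMAD6 (3.44 ± 0.12) and ID1 (0.68 ± 0.12). It also did so for 10 (10) of 13 primitive streak genes, with MIXL1 at 6.43 ± 0.34 and TBXT at 6.53 ± 1.07, and for ISL1 (8.71 ± 0.76). ISL1 had 1, 2 and 2 counts in the untreated knockdown libraries, under the floor of 3, so the size of its value is uncertain. TBXT had 10, 0 and 5 counts in untreated wild-type and 0, 5 and 10 in untreated knockdown libraries, so its size is uncertain too. The TBXT call was lost with all standard libraries thinned to one depth (edgeR adjusted p = 0.0954) or to transwell depth (0.0502). The interaction was negative for 15 (17) of 19 pluripotency genes, which as a list had not fallen in wild-type cells, with SOX2 at -5.51 ± 0.13 and PRDM14 at -3.95 ± 0.09. For the FGF and ERK list the interaction was positive in 10 (11) of 14 members, SPRY4 having fallen with BMP4 in wild-type cells and risen in knockdown cells (1.06 ± 0.07). These 4 lists held with an estimated correlation. The interaction was called for 6056 genes, 3027 positive and 3029 negative. Over 13026 genes the log2 responses of the 2 genotypes correlated with Pearson's r = 0.56, a value across genes, which are not independent replicates. Of the genes called in both, 1551 rose and 1817 fell in both genotypes, and 788 moved in opposite directions, fewer than the 1511 expected of independent lists.

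**Figure D2:**
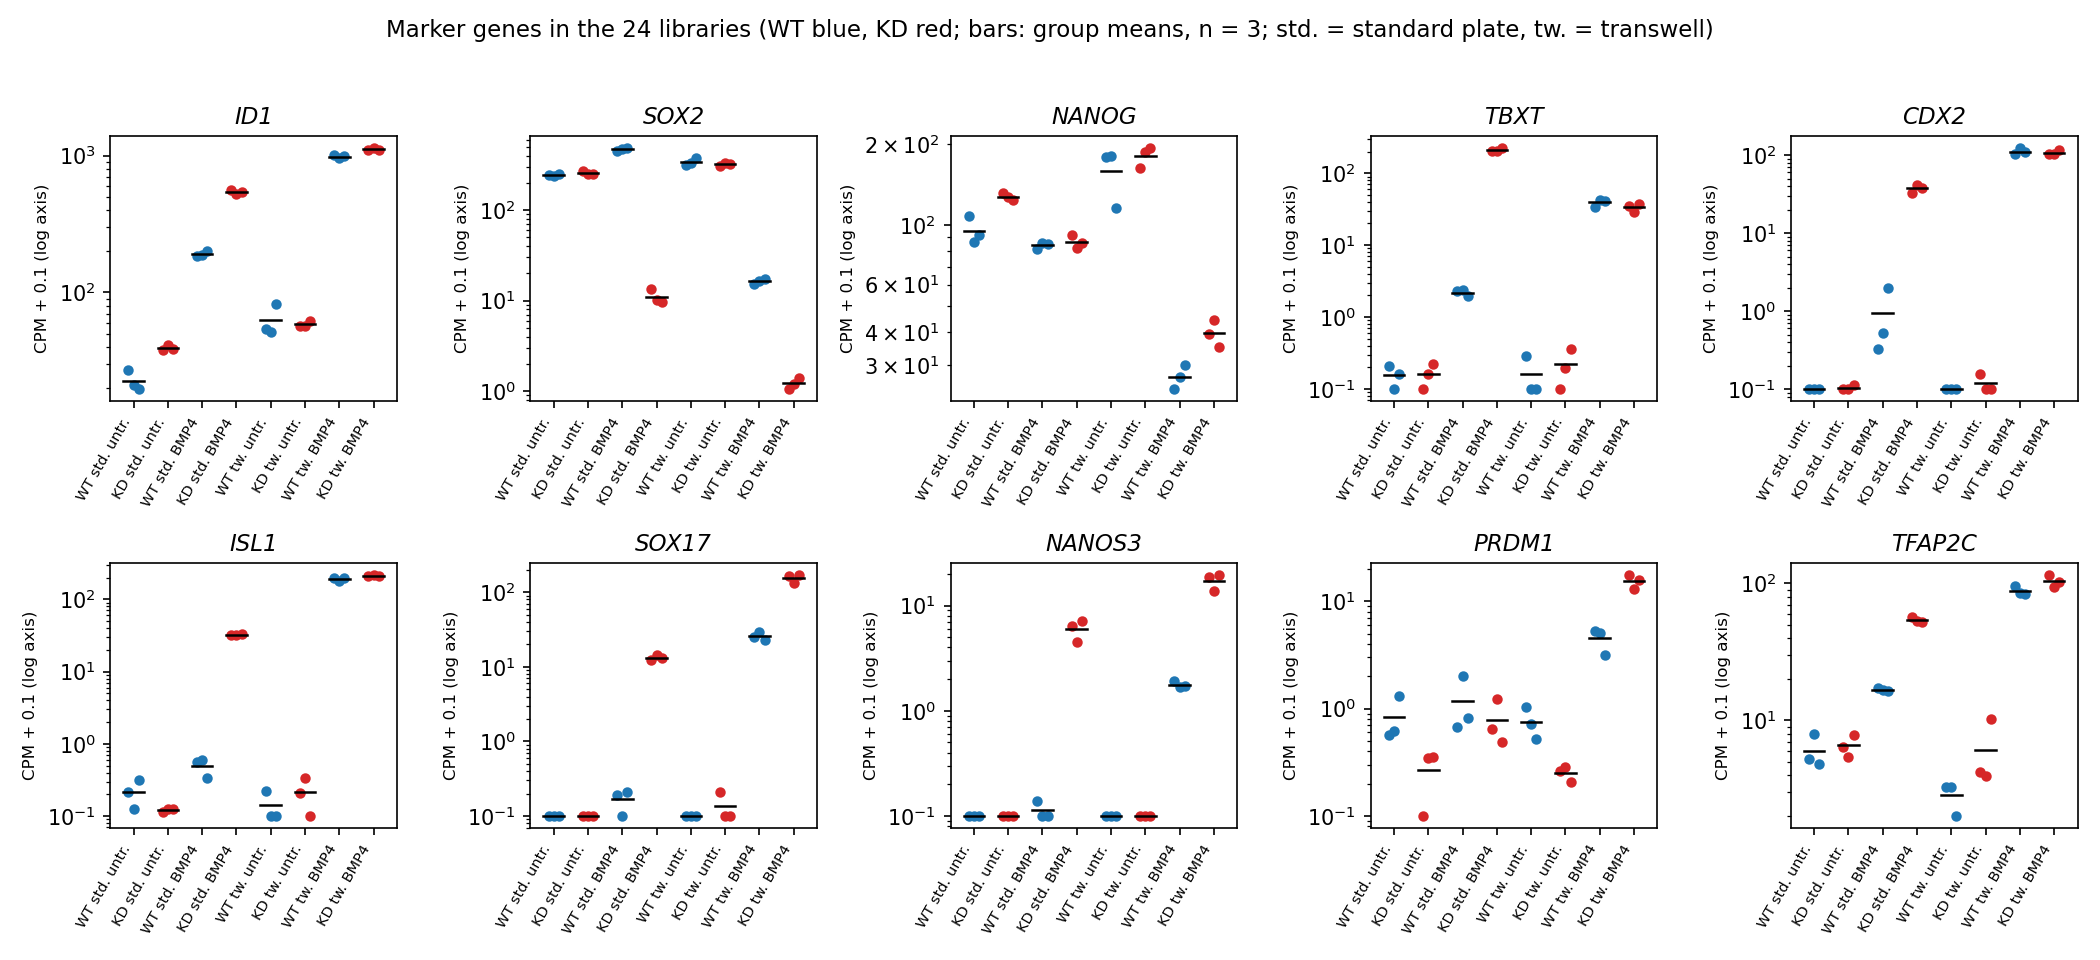
CPM of the 10 lineage, pluripotency and BMP marker genes in the 24 libraries, one panel per gene, on a log axis after adding 0.1 CPM. Points are libraries and bars group means; SOX2 lies near 466 CPM in BMP4-treated wild-type cells on standard plates and near 11 CPM in knockdown cells.

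The direct comparison of BMP4-treated cells on standard plates gave 7646 changed genes, 3656 higher and 3990 lower in the knockdown. Higher in the knockdown were 12 (13) of 13 primitive streak genes (EVX1 7.33 ± 0.14, MESP1 6.97 ± 1.08), 11 (11) of 15 amnion genes (GATA3 5.19 ± 0.19) and 8 (9) of 13 lateral and extraembryonic mesoderm genes (TBX3 6.60 ± 0.14). Of single genes CD48, a surface protein of blood cells, rose (7.63 ± 0.55), and the keratin pseudogene KRT16P2 (7.40 ± 0.64), whose counts are uncertain beside near-identical copies, rose too. The mucin gene MUC4, at 0 in all 3 knockdown libraries, was at least 162-fold lower. SOX2 (-5.42 ± 0.11), SOX21 (-9.59 ± 0.55) and HES3 (-8.47 ± 0.31) were lower, and the neural ectoderm list was not called (camera adjusted p = 0.463). Germ cell specification genes split, 4 (4) of 14 rising and 5 (6) falling: SOX17 (7.52 ± 0.62), NANOS3 (8.69 ± 0.79) and TFAP2C (1.69 ± 0.17) rose, PDPN (-0.96 ± 0.06), ALPL (-0.73 ± 0.05) and VENTX (-2.01 ± 0.16) fell, PRDM1 was not called, and the list was not called (camera adjusted p = 0.76). The wild-type counts were 3, 0 and 0 for NANOS3 and 7, 0 and 10 for SOX17, at or near the floor, so the sizes of both changes are uncertain. Meiotic and later germ cell genes did not rise, with 2 (2) of 7 falling, DAZL among them (-5.09 ± 0.48).

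Junction genes in the BMP4-treated knockdown cells moved in both directions, 11 (13) of 27 rising and 8 (8) falling, with CLDN10 at 3.84 ± 0.07 and CGNL1 at -1.34 ± 0.06. AEN, which encodes an exonuclease, was at -0.79 ± 0.05. WNT response (13 (13) of 16 rose), BMP response (13 (14) of 14) and mesenchyme and EMT genes (12 (12) of 17) were also called upwards. Of 14 called lists 7 held with an estimated correlation. Those were the BMP response, WNT response, primitive streak, lateral and extraembryonic mesoderm, amnion, mesenchyme and EMT, and pluripotency lists. The 7 others, among them adherens junction and desmosome genes (12 (13) of 20 rose and 5 (5) fell), had adjusted p from 0.0624 to 0.46.

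On transwells wild-type cells responded to BMP4 with amnion and mesoderm genes. All 14 (14) of 14 BMP response genes rose, ID1 going from 62.2 ± 17.0 to 985 ± 26.6 CPM, and pluripotency genes fell in 17 (17) of 19 cases, SOX2 going from 343 ± 32.6 to 16.2 ± 0.925 CPM and NANOG from 158 ± 37.5 to 27.1 ± 2.75 CPM. Amnion markers rose in 15 (16) of 16 cases and lateral and extraembryonic mesoderm markers in 12 (12) of 14, with ISL1 at 191 ± 8.62 CPM and HAND1 at 1337 ± 40.6 CPM. HAND1, WNT6, HOXB6 and CDX2 were at 0 before treatment and at least 7294-fold, 1130-fold, 682-fold and 607-fold higher after it. Of the germ cell genes, SOX17 reached 25.5 ± 3.02 CPM and NANOS3 1.68 ± 0.138 CPM, both from 0, and TFAP2C rose by 5.02 ± 0.33.

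Other groups in the wild-type transwell cells included trophoblast markers, 6 (6) of 9 rising with ENPEP at 6.72 ± 0.28 (adjusted p = 0.0933 with an estimated correlation), and definitive endoderm markers, 8 (8) of 10 (adjusted p = 0.0948 with an estimated correlation). Proliferation genes fell in 9 (9) of 15 cases, MCM2 at -1.60 ± 0.08 (adjusted p = 0.139 with an estimated correlation). Mitochondrially encoded genes rose in 12 (12) of 13 cases (adjusted p = 0.387 with an estimated correlation), their share of counts going from 2.00 ± 0.616% to 4.04 ± 0.553%. Of 15 called lists 7 held with an estimated correlation: amnion, lateral and extraembryonic mesoderm, BMP response, pluripotency, primitive streak, BMP ligands and receptors (11 (12) of 15 rose and 1 (1) fell), and WNT response. In total 9452 genes changed, 5148 of them by at least 2-fold.

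Knockdown cells on transwells responded to BMP4 as well. ID1 went from 58.7 ± 2.75 to 1112 ± 14.7 CPM, ISL1 reached 211 ± 2.65 CPM and SOX2 fell from 320.3 ± 10.3 to 1.13 ± 0.172 CPM. In total 9394 genes changed, 5181 by at least 2-fold, and 8 of 17 called lists held with an estimated correlation. Hypoxia and glycolysis genes rose in 15 (15) of 19 cases (camera adjusted p = 0.0246 with an estimated correlation), P4HA1 by 2.93 ± 0.09 and BNIP3 by 2.99 ± 0.15. Germ cell specification genes rose in 7 (7) of 13 cases, with PRDM1 at 6.58 ± 0.37 (adjusted p = 0.0982 with an estimated correlation). Across 12995 genes the responses of the 2 genotypes on transwells correlated with r = 0.94, and 43 called genes moved in opposite directions.

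**Figure D3:**
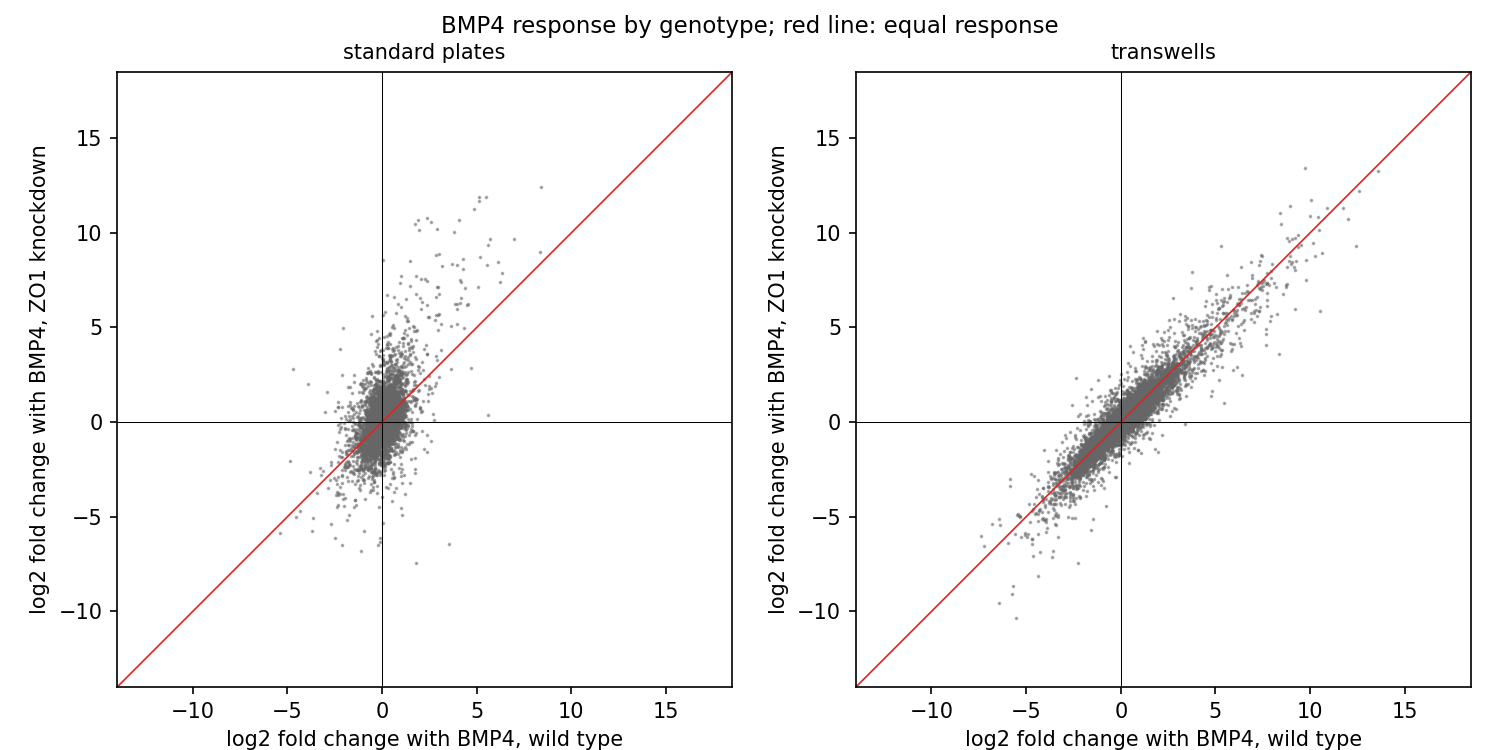
Log2 fold change with BMP4 in wild-type cells (x axis) against knockdown cells (y axis), one point per gene with average log2 CPM of at least 1 and no group at 0, on standard plates (left) and transwells (right). The points lie along the diagonal on transwells (r = 0.94) and spread along the y axis on standard plates (r = 0.56).

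Actin-linked genes were lower in the knockdown when untreated cells on transwells were compared. The actin and SRF list fell, 6 (10) of 15 members, with the smooth muscle genes TAGLN (-2.34 ± 0.15) and CNN1 (-1.56 ± 0.13) and tropomyosin, TPM1 (-1.09 ± 0.09). This was the 1 list of 5 called that held with an estimated correlation (adjusted p = 0.00887). YAP and TAZ targets fell in 6 (8) of 22 cases, CCN1 at -1.33 ± 0.09 and CCN2 at -0.98 ± 0.10 (list adjusted p = 0.0704 with an estimated correlation). PHLDA3 and CDKN1A were also lower. CDKN1A lost its call without any 1 of the 6 libraries (edgeR adjusted p from 0.06 to 0.161) without the low-count filter (0.0664) or with the replicate number as a block (0.0924). PHLDA3 lost it without wild-type replicate 2 or knockdown replicate 1 or 2 (edgeR adjusted p = 0.0585, 0.113 and 0.102) or with that block (0.0504). ZNF10 had the largest rise here too (4.79 ± 0.25), followed by NAALADL2 (4.60 ± 0.67) and the metallothioneins MT1G (3.00 ± 0.22) and MT1H (2.94 ± 0.30). ANXA1 (-3.68 ± 0.33), MYL7, an atrial myosin light chain (-3.28 ± 0.43), and the natriuretic peptide gene NPPB (-3.21 ± 0.37) had the largest falls after TJP1.

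PRDM1 was lower in untreated knockdown cells (-2.07 ± 0.43), a call lost without any 1 knockdown library or wild-type replicate 1 or 2 (edgeR adjusted p from 0.0682 to 0.168) and in one fit of all 24 libraries (0.191), and NANOS3 was at 0 in both groups. Neural ectoderm genes fell in 2 (2) of 6 cases, SOX3 and NES (adjusted p = 0.0704 with an estimated correlation), and no mitochondrially encoded gene was called although that list was (adjusted p = 0.588 with an estimated correlation). Mitochondrial genes held 2.00 ± 0.616% of wild-type and 2.86 ± 0.548% of knockdown counts. The count was 152 of 15527 genes, 51 higher and 101 lower. Wild-type untreated replicate 3 stood apart from its group on the second principal component of the transwell libraries, at -52.0 against 1.46 and -3.06. Without it 244 genes were called; the 6 libraries alone, where CDKN1A, PHLDA3, NES, NAALADL2 and NPPB were not called, gave 32, DESeq2 485 (233 higher and 252 lower) and all 24 libraries in one fit 617. The counts without knockdown replicate 1, 2 or 3 were 99, 93 and 91, and without wild-type replicate 1 the neural ectoderm list and 1 other lost their calls, leaving 3 lists. Without knockdown replicate 1 the neural ectoderm list lost its call too.

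Germ cell genes were higher in the knockdown after BMP4 on transwells. NANOS3, an RNA-binding regulator of primordial germ cells, was at 1.68 ± 0.138 CPM in wild-type and 17.2 ± 3.05 CPM in knockdown cells (3.31 ± 0.25). SOX17, a transcription factor of human germ cells and of endoderm, was at 25.5 ± 3.02 and 156 ± 19.8 CPM (2.56 ± 0.18), and PRDM1 (BLIMP1) at 4.44 ± 1.19 and 15.3 ± 2.25 CPM (1.74 ± 0.26). The PRDM1 call was lost in one fit of all 24 libraries (edgeR adjusted p = 0.0599). TFAP2C, at 87.8 ± 6.65 and 104 ± 9.81 CPM, was not called (edgeR adjusted p = 0.754). Of the germ cell specification list 4 (6) of 13 rose and 0 (0) fell; camera called it, and the adjusted p was 0.103 with an estimated correlation.

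Hypoxia and glycolysis genes rose together in the same comparison, 13 (15) of 19 with 0 (0) falling, among them the glycolytic enzymes PGK1 (0.95 ± 0.08) and ALDOC (0.87 ± 0.09) and EGLN3, a prolyl hydroxylase induced by hypoxia (1.55 ± 0.19). The mitochondrially encoded list was called downwards with no member called (adjusted p = 0.479 with an estimated correlation), and mitochondrial genes held 4.04 ± 0.553% of wild-type and 3.26 ± 0.33% of knockdown counts. CDKN1A was at -0.85 ± 0.17, a call lost without wild-type replicate 3 or knockdown replicate 2 or 3 (edgeR adjusted p = 0.0509, 0.0639 and 0.0655). Of 11 called lists 2 held with an estimated correlation, among them hypoxia and glycolysis (adjusted p = 0.00675). Amnion markers were lower in 7 (8) of 16 cases, IGFBP3 at -1.75 ± 0.10 and WNT6 at -1.32 ± 0.09 (adjusted p = 0.0794 with an estimated correlation). Endoderm list members split, CXCR4 (2.91 ± 0.33), GATA4 and GATA6 rising and FOXA2 (-3.32 ± 0.44) falling.

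FOXF1, a lateral mesoderm transcription factor, rose most (4.68 ± 0.24), followed by CRHBP (4.28 ± 0.58). LMO3, at 0 in all 3 knockdown libraries, was at least 1.88-fold lower, a call lost without any of the 6 libraries but wild-type replicate 1 (edgeR adjusted p from 0.0939 to 0.126) or with the replicate number as a block (0.0735). FOXD3 (-4.83 ± 0.57), FOXB1 (-4.45 ± 0.60) and SOX2 (-3.88 ± 0.14) fell. VIM, the mesenchymal intermediate filament, was 1.51 ± 0.08 higher with BMP4 although it had been -1.0 ± 0.08 in untreated cells. In all 1186 of 15527 genes changed, 608 higher and 578 lower. Leaving out any of the 6 libraries gave between 612 and 697, the 6 libraries alone 2695, DESeq2 1852 and all 24 libraries 2102.

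The interaction on transwells was called for 387 genes. PRDM1 had the largest positive value of the genes considered (3.81 ± 0.50), TAGLN was at 1.87 ± 0.21 and VIM at 2.51 ± 0.11. The PRDM1 value combines its knockdown effects of 1.74 with BMP4 and -2.07 in untreated cells. The latter rests on 3, 4 and 2 counts in knockdown and 15, 10 and 7 in wild-type libraries, and its call was lost without single libraries. SOX2 was negative (-3.75 ± 0.18), as were FOXB1 (-5.18 ± 0.71) and FOXD3 (-4.80 ± 0.61). ID1 was not called (edgeR adjusted p = 0.634) and neither was TBXT. For NANOS3, at 0 in all untreated transwell libraries, no interaction value can be given. The hypoxia and glycolysis list was positive in 7 (14) of 19 members, with PGK1 at 0.96 ± 0.11, and was the 1 list of 8 called that held with an estimated correlation (adjusted p = 0.00757). Without wild-type untreated replicate 3 the count was 778, and without each of the 9 BMP4-treated or knockdown libraries it lay between 177 and 222. DESeq2 called 901 and all 24 libraries in one fit 1089.

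**Figure D4:**
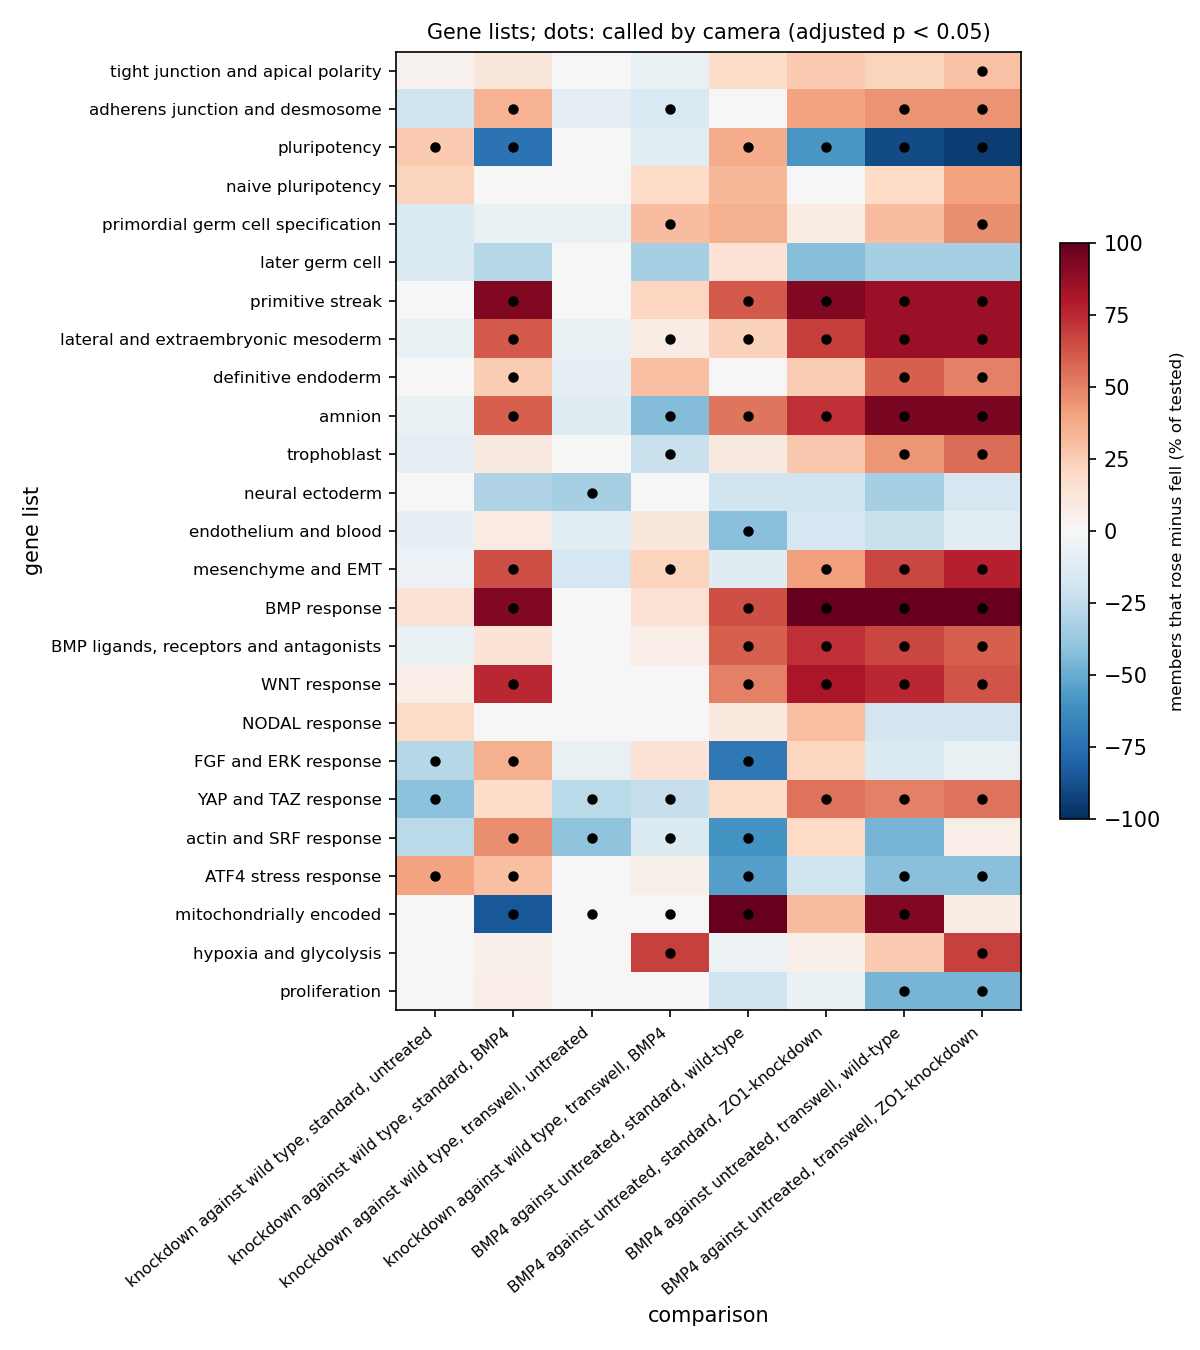
Net share of members that changed in each of 25 gene lists in the 8 comparisons within a culture format, as members that rose minus members that fell in percent of those tested. Dots mark lists called by camera with the preset correlation; 13 (15) of 19 hypoxia and glycolysis genes rose in BMP4-treated knockdown transwell cells.

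The effect of the knockdown differed between culture formats, which also differ in library protocol and depth. This was tested in fits of all 24 libraries. In untreated cells the difference of differences was called for 160 genes: the effect of the knockdown was lower on transwells for TAGLN (-2.26 ± 0.20), VIM (-1.90 ± 0.12), ACTA1 (-3.15 ± 0.32) and ACTG2 (-4.30 ± 0.38). For CDKN1A (1.28 ± 0.21) and AMOTL2 (1.02 ± 0.14) the fall was larger on standard plates. The actin and SRF list was negative in 5 (7) of 15 members and held with an estimated correlation (adjusted p = 0.00224). Without wild-type standard replicate 2 or 3 the count was 95 or 99, without knockdown standard replicate 1 or 2 106 or 98, and without knockdown transwell replicate 2 or 3 106 and 106. Without wild-type transwell replicate 1, 2 or 3 it was 432, 254 or 277, and DESeq2 called 600 (285 positive and 315 negative, against 95 and 65).

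With BMP4 the effect of the knockdown differed between culture formats for 3993 genes. The effect was lower on transwells for 13 (14) of 14 BMP response genes, ID1 at -1.37 ± 0.18 and BAMBI at -3.37 ± 0.16, for 10 (11) of 15 streak genes with TBXT at -6.93 ± 0.36 and for 12 (12) of 16 amnion genes. These 3 lists held with an estimated correlation. CDX2 (-5.52 ± 0.56) and ISL1 (-6.24 ± 0.29) were negative, while PRDM1 (2.38 ± 0.83) and SOX2 (1.52 ± 0.22) were positive. PRDM1 was low on standard plates, at 1.07 ± 0.746 and 0.689 ± 0.387 CPM in wild-type and knockdown cells, and its call was lost without any 1 BMP4-treated transwell library, wild-type standard replicate 2, or knockdown standard replicate 1 or 3 (edgeR adjusted p from 0.0618 to 0.179) and without the low-count filter (0.0606).

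The BMP4 response itself differed between culture formats for 7849 genes in wild-type cells and 5398 in knockdown cells. In wild-type cells the difference between the responses, transwell minus standard, was negative for 19 (19) of 19 pluripotency genes, SOX2 at -5.34 ± 0.15 and NANOG at -2.35 ± 0.18, and 13 (14) of 14 BMP response genes had a positive value, ID1 at 0.91 ± 0.18, both lists holding with an estimated correlation. In knockdown cells the pluripotency value was negative for 15 (15) of 19, SOX2 at -3.60 ± 0.19 and NANOG at -1.62 ± 0.17, and BMP response genes split, 6 (7) positive and 2 (2) negative of 14 (adjusted p = 0.0806 with an estimated correlation). TBXT was raised more on standard plates in knockdown cells (-3.52 ± 1.19) and more on transwells in wild-type cells (4.21 ± 1.14). Both sizes are uncertain, since TBXT had only 0 to 10 counts in each untreated library. The former call was lost without knockdown transwell untreated replicate 2 or 3 (edgeR adjusted p = 0.0657 and 0.427) or with the replicate number as a block (0.0563), and the latter without wild-type standard untreated replicate 1 (0.0881) and with thinning to transwell depth (0.347). Of 2741 genes raised at least 2-fold by BMP4 in wild-type transwell cells and tested on standard plates, 913 rose in wild-type and 1898 in knockdown standard cells. Their median log2 fold changes were 0.29 and 0.89, or 0.28 and 0.89 with genes at 0 in a whole group put at their bound.

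**Figure D5:**
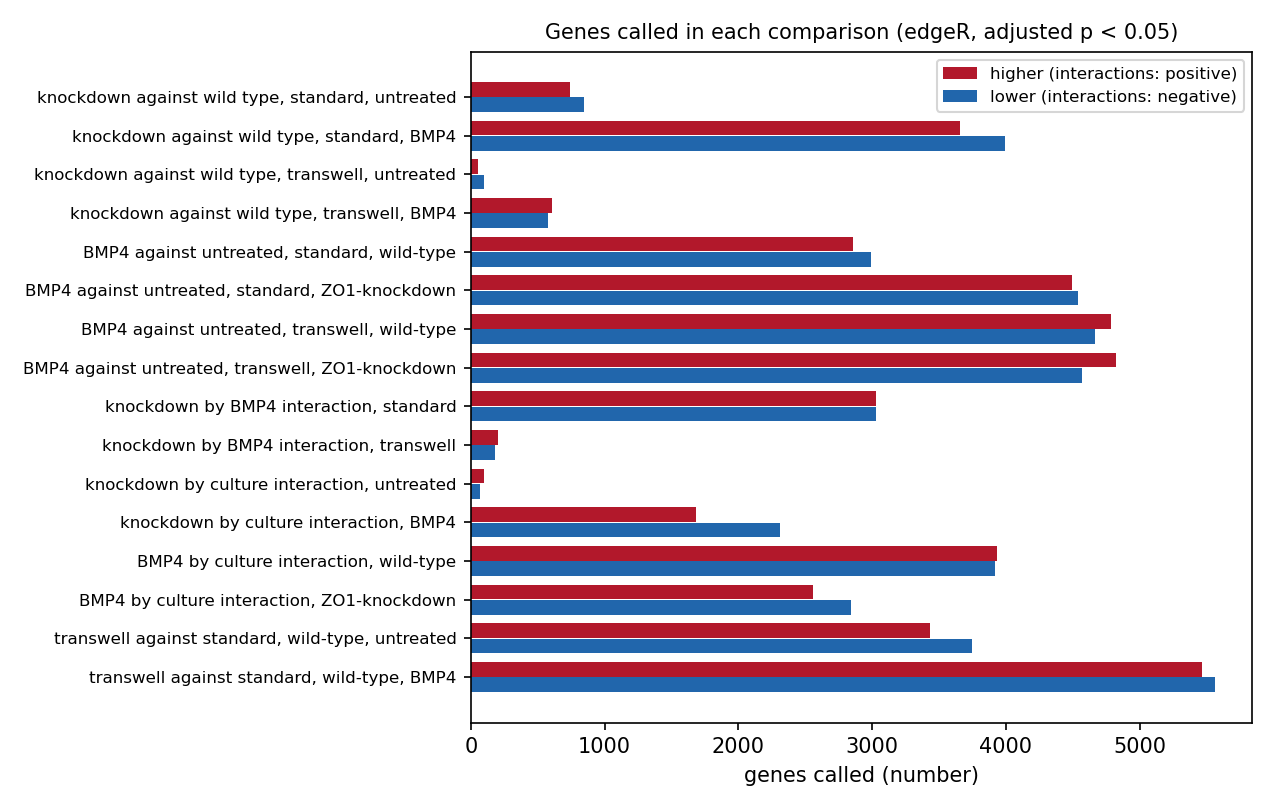
Number of genes called higher and lower (adjusted p under 0.05) in each of the 16 comparisons, horizontal bars starting at 0. The bars range from 51 genes higher with the knockdown in untreated transwell cells to 5566 lower in transwell against standard wild-type cells with BMP4.

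Wild-type cells on transwells and on standard plates were also compared directly, although library protocol and depth differed with the format. Untreated cells differed in 7179 genes and BMP4-treated cells in 11033. Camera called 5 of 26 lists in untreated cells and 17 with BMP4, of which 2 and 11 held with an estimated correlation. Pluripotency genes were higher on transwells in untreated cells, 13 (14) of 19 with SOX2 at 0.54 ± 0.10, and lower with BMP4, 18 (18) of 19 with SOX2 at -4.80 ± 0.12. With BMP4 all 16 (16) amnion genes tested and 13 (14) of 14 BMP response genes were higher on transwells, ISL1 at 8.97 ± 0.26 and TBXT at 4.29 ± 0.26. The largest falls in untreated cells included pseudogenes with near-identical parent genes, whose counts are uncertain, such as FABP5P7, at 0 on transwells and at least 187-fold lower. ENSG00000204531 (POU5F1) was listed at only 4.19 ± 1.36 CPM in untreated wild-type standard cells and 5.90 ± 1.48 CPM on transwells. It has near-identical copies among the annotated genes, so its values are uncertain and no change of it is drawn on here.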

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

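The interaction tests below were set before the data were examined. The tests of explanations, the thinning of libraries and the counts of other splits were chosen after the results were seen.

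The response to BMP4 differed between genotypes on standard plates for 6056 genes. The differences in log2 response were 3.56 for BAMBI, 3.44 for SMAD6, 0.68 for ID1, 8.71 for ISL1, 6.43 for MIXL1, 6.53 for TBXT, -3.95 for PRDM14 and -5.51 for SOX2. The ISL1 value is uncertain, at 1 or 2 counts per untreated knockdown library. TBXT had 0 to 10 counts in each untreated library, so the sizes of its BMP4 response differences, here and between formats below, are uncertain. On transwells 387 genes differed, with PRDM1 at 3.81, VIM at 2.51, TAGLN at 1.87, PGK1 at 0.96, SOX2 at -3.75, FOXD3 at -4.80 and FOXB1 at -5.18. The PRDM1 value includes a knockdown effect of -2.07 in untreated cells, at 2 to 4 counts per knockdown library. The effect of the knockdown differed between culture formats for 160 genes in untreated cells, with ACTG2 at -4.30, ACTA1 at -3.15, TAGLN at -2.26, VIM at -1.90, CDKN1A at 1.28 and AMOTL2 at 1.02. With BMP4 it differed for 3993 genes, with TBXT at -6.93, ISL1 at -6.24, CDX2 at -5.52, BAMBI at -3.37, ID1 at -1.37, SOX2 at 1.52 and PRDM1 at 2.38. The BMP4 response differed between formats for 7849 genes in wild-type cells (SOX2 -5.34, NANOG -2.35, ID1 0.91, TBXT 4.21) and for 5398 genes in knockdown cells (SOX2 -3.60, NANOG -1.62, TBXT -3.52). Single libraries ended 3 of these calls: PRDM1 with BMP4 (edgeR adjusted p up to 0.179, without wild-type standard replicate 2, and over 0.05 without any of 8 others), TBXT in wild-type cells (0.0881 without untreated standard replicate 1) and TBXT in knockdown cells (0.0657 and 0.427 without untreated transwell replicate 2 or 3). Every difference between formats also spans 2 library protocols.

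On standard plates BMP4 raised SOX2 in wild-type cells and lowered it in knockdown cells. Wild-type cells that never received BMP4 are argued against by the 10 of 14 BMP response genes that rose in them, and a difference in depth by the 5355 interaction genes called with all standard libraries thinned to one depth. TBXT lost its call there (6.53 ± 1.07 before, 5.11 ± 2.27 after), its untreated level leaving few counts at that depth. A small fixed share of wild-type cells responding as knockdown cells did, the others not responding, would move genes the same way in both genotypes. Of 4156 genes changed in both, 788 (19.0%) moved in opposite directions, which such a share alone would not give for those genes. A bound of 5% for this count was set after the value was seen, so passing it decides nothing. The count replaced a test that was undecided. There BMP response genes rose in wild-type cells by a median 4.57% of the rise in knockdown cells. Primitive streak genes rose by 2.01% of it (permutation test p = 0.27). Opposite moves were fewer than the 1511 expected of independent lists, and 1551 genes rose and 1817 fell in both genotypes, so a response common to both genotypes in part is not excluded. Doxycycline cannot be told apart from the loss of ZO1, since 0 wild-type libraries had it. A BMP4 duration that differs between genotypes stays open too, since the labels used here give one for 0 of the knockdown libraries. A change in how BMP4 reaches its receptors without ZO1 may be a biological explanation. On transwells, which give access to the basal side, the interaction held 387 genes. The responses of the genotypes correlated there with r = 0.94, against 0.56 on standard plates, as that explanation would give. The responses of knockdown cells in the 2 formats correlated with r = 0.82 but differed for 5398 genes. With BMP4 the summed HOX level was 7.69 CPM in knockdown standard cells, against 203 CPM in knockdown and 298 CPM in wild-type transwell cells. Equal access in those groups would not by itself give that gap, which also spans 2 library protocols. Depth differs with the format, but the 5355 genes with all standard libraries at one depth argue against depth alone as the source of the lower transwell count. That count ranged from 177 to 778 when 1 library was left out. In simulated counts 1.5-fold interactions were recovered in 8.96% of cases on transwells and 37.3% on standard plates. The 2 counts are therefore not on one scale. Library protocol differs with the format too, so the explanation by receptor access stays open. BMP4 given from one side of the cells at a time, with 1 library protocol, would test it.

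Germ cell genes were higher in BMP4-treated knockdown cells on transwells, with NANOS3 at 3.31, SOX17 at 2.56 and PRDM1 at 1.74 on the log2 scale. A generally larger BMP4 response was set against the BMP response genes, whose highest log2 fold change was 1.06, below that of PRDM1, with 2 of 14 called. That shows only that BMP response genes did not rise as much as these 3 germ cell genes. PRDM1 was taken as the mark after the values were seen, and TFAP2C, which was not called, was left out. Camera did not call the list, although fry did. All its members had already risen with BMP4 in wild-type transwell cells, so log2 changes of the 2 sets need not match. A generally larger response is therefore not decided. Definitive endoderm in place of germ cells stays open: FOXA2 was at -3.32, which that explanation would not give, but CXCR4, GATA4 and GATA6 rose (2.91, 2.28 and 1.54). Those genes were looked at, and the bound was tightened to cover them, after the values were seen. An increase in germ cell fate is the biological candidate explanation and rests on 3 genes, with TFAP2C not called and PRDM1 not called in one fit of all 24 libraries (edgeR adjusted p = 0.0599).

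ZNF10 was higher in all 4 knockdown comparisons. A repressor transgene that carries a part of ZNF10, as some doxycycline-dependent knockdown systems use, may be the source of those reads. Among the 5 measured genes within 100 kb none rose in any of the 4 comparisons, and the highest log2 fold change in untreated standard cells was 0.22. A change of the endogenous gene alone would give the same values, so the explanations cannot be told apart by gene-level counts.

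Other splits of the libraries were refitted for each count of genes. Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and in each only 1 split, the real one, gave as many genes. The highest other split gave 1 gene, against 1583 and 7646 for the knockdown on standard plates (untreated and BMP4), 1186 for the knockdown on transwells with BMP4, 5854, 9039, 9452 and 9394 for BMP4 (standard wild type and knockdown, transwell wild type and knockdown) and 11033 for transwell against standard with BMP4. It gave 2 against 152 for the knockdown in untreated transwell cells and 282 against 7179 for transwell against standard in untreated cells. For each interaction 1 of 24 drawn splits, the real one, gave as many genes, the smallest share that 24 draws can give. Drawn splits move libraries between groups that differ by real main effects, so they are not draws from data without an interaction. The share therefore does not decide whether chance could give a count, and no allowance was made for testing 6 interactions. The number of draws had been lowered after a first set was seen. The real and highest other counts were 6056 and 4476 for knockdown by BMP4 on standard plates, 387 and 258 on transwells, 160 and 154, a narrow margin, for knockdown by culture in untreated cells, 3993 and 3296 with BMP4, and 7849 and 7681 for BMP4 by culture in wild-type cells and 5398 and 1771 in knockdown cells. Many drawn splits keep part of the true labels and with them part of the real difference, which the high counts of other splits include.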

How the results depend on the processing

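The alternatives other than thinning were planned. Thinning was chosen after the results were seen. RLE scaling, either low-count filter and thinning moved no count of genes by more than 1.5 times. At an adjusted p under 0.01 the knockdown changed 712 genes in untreated standard cells, 76 in untreated transwell cells and 509 in BMP4-treated transwell cells, BMP4 changed 3874 in wild-type standard cells, and the interactions held 111 (transwell), 60 (culture, untreated) and 2599 genes (culture, BMP4). With a 2-fold minimum the knockdown counts were 204 and 2316 on standard plates and 78 and 438 on transwells (untreated and BMP4). The BMP4 counts were 1091 and 3052 on standard plates and 5148 and 5181 on transwells (wild type and knockdown). The interactions gave 2207 and 246 for knockdown by BMP4 (standard and transwell), 75 and 1996 for knockdown by culture and 4332 and 2468 for BMP4 by culture, and the formats differed in 2434 and 5724 genes. Both thresholds lower counts by construction. DESeq2 called 2499 genes for the knockdown in untreated standard cells, 485 and 1852 on transwells, 901 for the transwell interaction and 600 for knockdown by culture in untreated cells. One fit of all 24 libraries gave 705, 617 and 2102 for those knockdown comparisons, 3843 for BMP4 in wild-type standard cells and 1089 for the transwell interaction. The 6 libraries alone gave 32 and 2695 for the knockdown on transwells. The causes were not tested.

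Leaving out 1 library gave 943 to 1191 genes for the knockdown in untreated standard cells, 91 to 244 and 612 to 697 on transwells (untreated and BMP4), 177 to 778 for the transwell interaction, 95 to 432 for knockdown by culture in untreated cells and 3 to 7 lists for the knockdown in untreated transwell cells. The wild-type untreated transwell libraries raised counts when left out: replicate 3 gave 244 and 778 for the knockdown and the transwell interaction, and replicate 1 gave 432 for knockdown by culture. Other left-out libraries that moved a count by over 1.5 times lowered it, as fewer libraries do. With an estimated correlation 3 lists were called for the knockdown in untreated standard cells and 7 with BMP4, 1 and 2 on transwells, and 7 and 8 for BMP4 on transwells. Fry called 8, 22 and 18 lists for the first 2 and the last of those knockdown comparisons, 23 for BMP4 in knockdown standard cells and 26 in wild-type transwell cells. Without a low-count filter 8 lists were called for the knockdown in untreated standard cells. Of 1524 values of named genes, 1 per alternative refitted and named value, 1493 kept their direction and side of the threshold, 31 lost the call and 0 reversed. All fits without 1 library count there as 1 value, the least favourable, and 9 of 176 lost the call. Genes removed by a filter are not counted. Most named values were chosen for size or adjusted p, and 171 of 176 were called, so they do not speak for all calls. Of all knockdown calls in untreated transwell cells the 6 libraries alone kept 19.7%. One fit of all 24 libraries kept 42.4% of those in untreated standard cells. Leaving out 1 library kept 49.6% to 56.7% of those in BMP4-treated transwell cells. DESeq2 kept 99.4% to 100% in the 4 knockdown comparisons.

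The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated between -0.029 and 0.0337 on standard plates and between -0.0551 and 0.0429 on transwells, and 5 of 24 libraries correlated best with their own number. With the number as a block the knockdown counts were 1437, 7505, 107 and 990, and no count moved by more than 1.5 times. 4 named calls were lost under the block (CDKN1A and PHLDA3 in untreated transwell cells, LMO3 with BMP4, and TBXT for BMP4 by culture in knockdown cells). Length offsets were not run, since the files give no lengths. Thinned to transwell depth, the standard libraries gave 1310 genes for the knockdown in untreated cells, against 1583 at full depth and 152 on transwells, so depth alone does not give the low count there. CLIC5, ANKRD1, GATA5 and the TBXT interaction lost their calls with all standard libraries at one depth. Their log2 values there kept their direction, at 1.98, -2.48, -2.64 and 5.11. CLIC5 also lost its call at full depth when single libraries were left out.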

Other observations

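The 2 gene families below were chosen after their values were seen, so both are observations and not tests of a plan. Metallothionein genes, which encode small metal-binding proteins, were higher in knockdown cells in all 4 comparisons with wild type. On standard plates 6 of 7 rose in untreated cells and 6 of 7 with BMP4, and on transwells 5 of 6 and 6 of 6, with the same numbers under RLE scaling and DESeq2. Their summed level was 77.7 ± 13.2 CPM in wild-type and 156 ± 4.44 CPM in knockdown cells untreated on standard plates (SD, n = 3), and 28.6 ± 3.52 and 75.0 ± 8.13 CPM with BMP4. On transwells it was 49.0 ± 15.6 and 149.7 ± 35.2 CPM untreated and 35.7 ± 0.468 and 227 ± 11.2 CPM with BMP4. BMP4 lowered them on standard plates, 7 of 7 in wild-type and 5 of 7 in knockdown cells, and raised 4 of 6 in knockdown cells on transwells. In wild-type cells on transwells 1 rose and 1 fell of 6. Members are near-identical in sequence, so the sum is firmer than any one of them. Doxycycline differs with genotype in every one of these comparisons.

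HOX genes, which pattern the body axis, came on with BMP4 on transwells. 16 of 17 tested rose in wild-type cells and 17 of 17 in knockdown cells. On standard plates 5 of 5 rose in knockdown cells (4 with DESeq2) and 0 of 5 in wild-type cells, by edgeR and by DESeq2. HOX genes were at or near 0 in untreated cells. The 17 passed the low-count filter only through BMP4-treated groups, and the 5 only through the BMP4-treated knockdown group. These counts of rising genes were therefore largely fixed by the filter. The summed level of all HOX genes reached 298 ± 19.2 CPM in wild-type and 203 ± 10.9 CPM in knockdown transwell cells with BMP4. HOXB2 and HOXB6 took most of it, at 102 and 125 CPM in wild-type cells. On standard plates with BMP4 the sum was 7.69 ± 0.349 CPM in knockdown and 0.137 ± 0.0776 CPM in wild-type cells. TBXT did not follow that order, at 209 ± 10.4 CPM in knockdown cells on standard plates and 39.4 ± 4.47 CPM in wild-type cells on transwells with BMP4. Culture format here also means library protocol and depth.

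The sign of a list's median, mean and camera test differed in 34 of 208 tests in the 8 comparisons within a culture format, and 0 of those were called.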
